A study of Mus musculus with 20 samples.

How the data were processed

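Whole-lung RNA was sequenced in 20 libraries, 5 biological replicates in each of 4 groups: wild type given saline, wild type given house dust mite (HDM), mice labelled Alox15 knockout given saline and mice labelled Alox15 knockout given HDM. Per the labels' protocols, libraries were made from oligo-dT selected RNA with the dUTP method, which keeps the strand; the same text also mentions removal of ribosomal RNA. Per the submitters' processing notes, the authors aligned reads with Bowtie2 2.1.0 and estimated expression with RSEM 1.2.15, and the genome build named there is hg38, a human build, although the table lists mouse gene symbols. The build that was used is therefore not known, and no coordinates are given. The authors deposited expected counts per gene and library, estimated by RSEM and not normalized. RSEM shares reads that match several genes among them, so members of multigene families (globins, major urinary proteins, Chil3 and Chil4, ribonucleases, mast cell proteases) are uncertain one by one.

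Expected counts were rounded to whole numbers. The ribosomal transcript Rn45s took 1.21% to 6.08% of the counts of a library. At this depth 1 CPM is more than 10 counts, and a floor of 3 counts over a group was used where a group had 0 counts; such bounds cover counting error only. Genes were filtered with edgeR's filterByExpr by group, which left 16193 of 24054 genes. Counts were scaled with TMM factors and fitted in R 4.3.3 with edgeR 4.0.16, with a mean for each group, all 20 libraries sharing the estimate of spread over 16 residual degrees of freedom. The robust quasi-likelihood F test gave 5 comparisons: HDM against saline in each genotype, knockout against wild type under each treatment, and the interaction. P-values were adjusted by Benjamini-Hochberg within a comparison, and genes with an adjusted p under 0.05 are those called, or said to have risen or fallen. Log2 fold changes are shown with their standard error where given after ±, and CPM as mean ± SD.

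The 33 gene lists of inflammatory programmes, cell types, tissues and stress responses were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Each list was tested with limma 3.58.1's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. For each list the number of members past the test is given over all genes and, where it differs, adjusted over the list alone. List scores (mean log2 CPM of members per library, prior count 2) were compared with exact two-sided permutation tests, as was Alox15. Named genes are Alox15, the 10 genes with the largest rise and the 10 with the largest fall in each comparison (adjusted p under 0.05, mean log2 CPM of 1 or more, no overlap between groups except for the interaction, predicted genes and receptor segments left out), up to 4 passing members per list, and Nnt, Xist, Ddx3y and Eif2s3y as checks of strain and sex. Other genes named were chosen after their values were seen. Chromosome and gene order come from RefSeq genes of mouse assembly GRCm38.p6, which placed 99.5% of tested genes and 1312 on chromosome 11.

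The scripts were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. Each gene was drawn independently, with no variation shared between genes, such as a varying content of another tissue. The rates that follow therefore need not hold for the real libraries, where genes can move together. For HDM against saline in wild type (16086 genes), 81.0% of 2-fold and 95.0% of 4-fold changes were found and 3.28% of calls were false; for HDM in knockout (16089 genes) these were 79.0%, 93.0% and 4.40%, for knockout under saline (16112 genes) 66.0%, 90.0% and 4.82%, for knockout under HDM (16082 genes) 77.0%, 87.0% and 4.60%, and for the interaction (16096 genes) 60.0%, 81.0% and 6.00%. The changed list was called in each of the first 4, and 1 unchanged list was also called for knockout under HDM. Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma voom, the 10 compared libraries alone, a replicate block, stricter thresholds and leaving out each library; added after the data were seen were fits without the libraries with an Adipoq level of 50 CPM or more, with an adipose covariate, without Rn45s, with a length offset, without liver markers and without chromosome 11. A liver marker list and a list of unfolded protein response and endoplasmic reticulum export genes were also made after the data were seen.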

Results

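RNA sequencing measured gene expression in whole lung of female C57Bl6 mice. The 20 libraries form 4 groups of 5 biological replicates, from wild-type mice and mice labelled Alox15 knockout that received saline or house dust mite (HDM). HDM is an airborne allergen that causes allergic airway inflammation when it is inhaled, and it was given into the nose daily for 14 days. Alox15 encodes a lipoxygenase that oxidises polyunsaturated fatty acids. The groups are written WT_saline, WT_HDM, KO_saline and KO_HDM. Total expected counts were 15601878 to 21715842 in WT_saline, 12573113 to 20662632 in WT_HDM, 21120878 to 23305673 in KO_saline and 17840138 to 21082770 in KO_HDM. The table lists 24054 genes, and 16193 had enough counts to be tested. Xist, which is expressed from the inactive X chromosome, was found in every library, and the Y-linked genes Ddx3y and Eif2s3y had at most 2 counts in any of them. The ribosomal transcript Rn45s took 1.47% to 3.47% of the counts in WT_saline, 2.72% to 6.08% in WT_HDM, 1.21% to 2.26% in KO_saline and 1.82% to 2.98% in KO_HDM. Nnt, which is disrupted in a common C57BL/6 substrain, lay between 20.2 and 33.5 CPM (counts scaled to the size of the library) in all 20 libraries.

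Alox15 itself was higher, not lower, in the libraries labelled knockout. WT_saline libraries held 4.58 ± 4.00 CPM (SD, n = 5; range 0.825 to 11.1), and WT_HDM libraries held 18.6 ± 8.53 CPM (7.92 to 29.8). KO_saline libraries held 40.8 ± 2.45 CPM (38.4 to 44.7) and KO_HDM libraries 41.1 ± 4.07 CPM (35.0 to 45.5), so the groups labelled knockout did not overlap with either wild-type group. Under saline the log2 fold change of knockout labels over wild type was 3.15 ± 0.45 (SE), with an edgeR adjusted p of 0.000583 and an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 libraries can give. Under HDM it was 1.15, with the same exact p of 0.00794 but an edgeR adjusted p of 0.107, which fell to 0.0462 and 0.0453 without WT_saline 1 or WT_saline 2. HDM raised Alox15 in wild-type lungs by 2.01 ± 0.44 on the log2 scale (adjusted p = 0.0024; exact permutation p = 0.0159, n = 5), or by 2.63 without WT_saline 2, while the difference was 0.01 in the libraries labelled knockout (adjusted p = 0.987). Counts per gene do not show which exons the reads came from, and some knockout alleles still make a transcript. Because the targeted gene does not fall with the label, every direction between genotypes below is that of libraries labelled knockout over libraries labelled wild type.

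**Figure D1:**
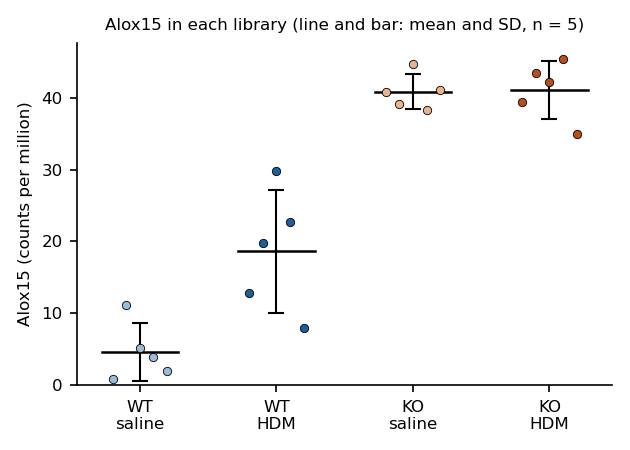
Alox15 level in CPM in each of the 20 libraries, by group, with the mean and SD of 5 libraries as a line and bar. The libraries labelled knockout sit between 35.0 and 45.5 CPM, above every wild-type library, of which the highest holds 29.8 CPM.

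The first question is what repeated HDM does to the lung of wild-type mice. Genes of alternatively activated macrophages and mucous cells were among those that rose most. Chil4, a chitinase-like protein whose reads may be shared with its near-identical neighbour Chil3, went from 2.58 ± 2.13 to 1088 ± 880 CPM (SD, n = 5), with a log2 fold change of 8.75 ± 0.87 (8.15 without WT_HDM 3). Mmp12, the elastase of macrophages, rose from 6.11 ± 1.10 to 778 ± 332 CPM. The chloride channel regulator now named Clca1, listed here under its older symbol Clca3, rose from 60.5 ± 48.2 to 3375 ± 1265 CPM, and the airway mucin Muc5ac from 8.64 ± 3.96 to 431 ± 281 CPM. Rnase2a, an eosinophil-associated ribonuclease of a multigene family, rose from 0.0394 to 31.9 ± 14.8 CPM. Fbp1 (6.22), Dcstamp (5.98), Itln1 (6.55; 7.39 without WT_saline 2 and 5.84 without WT_HDM 3) and Capn9 (6.90; 7.52 without WT_saline 1) rose as well on the log2 scale. Mcpt1, a mast cell protease of another multigene family, had 1 count over the 5 WT_saline libraries and a mean of 6.84 ± 4.96 CPM under HDM.

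Of 14 measured genes of alternative macrophage activation, 11 rose (12 adjusted over the list alone), among them Arg1 (5.72), Retnla (4.56) and Chil3 (4.12); the list's adjusted p was 1.69e-28, and 0.00044 with an estimated correlation. Goblet cell and mucus genes rose in 15 of 16 (adjusted p = 1.22e-14; 0.091 with an estimated correlation). Type 2 cytokines, chemokines and receptors rose in 8 of 16 members (9 adjusted over the list alone), including the eosinophil attractants Ccl24 (3.71) and Ccl11 (2.98) and their receptor Ccr3 (2.85); the list had adjusted p = 4.67e-06, or 0.0671 with an estimated correlation. Il5 did not pass, at 0.67 and 0.57 CPM. Monocyte and interstitial macrophage markers rose in 10 of 17 (Trem2 3.46, Gpnmb 2.61, Ms4a7 2.49), with an adjusted p of 3.78e-13 and 0.0607 with an estimated correlation. Alveolar macrophage markers went both ways, 7 higher (Ctsk 2.96, Olr1 2.33) and 3 lower (Fabp1 -2.83), under an upward call (adjusted p = 1.79e-06; 0.0662 with an estimated correlation). Cell cycle genes rose in 18 of 20 (19 adjusted over the list alone), such as Mki67 (1.99) and Top2a (1.95), and matrix genes in 11 of 20, such as Timp1 (3.12) and Tnc (1.46). Their adjusted p were 1.93e-13 and 1.24e-08, and 0.168 and 0.114 with an estimated correlation. MHC class II genes rose in 8 of 10 (9 adjusted over the list alone; adjusted p = 2.75e-06; 0.247 with an estimated correlation). B and plasma cell genes rose in 6 of 15 (7 adjusted over the list alone), such as Igj, now Jchain (3.71), with an adjusted p of 3.72e-05 and 0.422 with an estimated correlation. That list's mean log2 change of 1.58 was 2.26 without WT_saline 4, a saline library with high lymphocyte markers. Eosinophil markers were 6 higher and 2 lower of 9 (adjusted p = 0.0207; 0.091 with an estimated correlation), and the call ended without WT_saline 2 (adjusted p = 0.0552), WT_HDM 2 (0.0531) or WT_HDM 5 (0.0564).

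Several club cell and endothelial genes were lower under HDM in wild-type lungs. The club cell cytochrome Cyp2f2 fell from 2312 ± 521 to 558 ± 169 CPM (SD, n = 5; log2 -2.05 ± 0.23), and the club cell secretoglobin Scgb1a1 by 1.40 on the log2 scale. Pon1 (-2.88), Gdpd2 (-2.53), Scgb1c1 (-2.44) and Bex2 (-2.25) were among the genes that fell most, beside Cst8 (-3.49; -4.23 without WT_HDM 5). Club cell markers fell in 8 of 12, with 1 higher (adjusted p = 4.67e-06; 0.136 with an estimated correlation), and ciliated cell markers in 7 of 17 (9 adjusted over the list alone; adjusted p = 0.000896; 0.48 with an estimated correlation). Endothelial markers fell in 12 of 19 (14 adjusted over the list alone), such as Kdr (-1.16) and Ednrb (-0.99), and type 1 alveolar markers in 5 of 14 (7 adjusted over the list alone). Their adjusted p were 5.21e-06 and 0.00275, against 0.422 and 0.608 with an estimated correlation. NK and cytotoxic genes fell in 8 of 12 (10 adjusted over the list alone), such as Klrb1c (-1.10) and Prf1 (-1.03), with an adjusted p of 0.000207 and 0.248 with an estimated correlation. All 11 red blood cell genes were lower (adjusted p = 6.06e-06; 0.356 with an estimated correlation), such as Alas2 (-1.19). Mast cell and basophil genes were split, with Mcpt1 and Mcpt2 higher and Gata2 (-1.08) and Hdc (-0.58) lower; the list was not called, and its median of -0.58 and mean of 0.99 had opposite signs. Clock genes were split as well, with Dbp (1.24) and Bhlhe41 (1.24) higher and Npas2 (-1.62) and Arntl (-1.37) lower, and that list was not called. Skeletal muscle genes were high in WT_HDM 2, where Ckm lay at 414.5 CPM against at most 46.4 CPM in the other 19 libraries; that list was not called.

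In total edgeR called 4866 genes at an adjusted p under 0.05, with 2198 higher and 2668 lower, and 1077 of them changed at least 2-fold, 795 higher and 282 lower. Of the 33 lists, 16 were called with the preset correlation and 1, alternative macrophage activation, also with an estimated correlation. The libraries of both groups did not overlap for 1874 genes (11.6% of those tested), against 0.794% by chance. In the 10 libraries of this comparison alone, 2854 genes were called. The Rn45s share was 2.72% to 6.08% in WT_HDM against 1.47% to 3.47% in WT_saline.

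The same question was asked in the libraries labelled knockout. Clca3 rose from 3.12 ± 1.79 to 2417 ± 1259 CPM (SD, n = 5), Muc5ac from 6.30 ± 1.61 to 539 ± 434 CPM (log2 6.42; 5.78 without KO_HDM 5), and Mmp12 from 14.6 ± 3.63 to 440 ± 107 CPM. Chil4 rose by 9.48 on the log2 scale (10.29 without KO_saline 1), Itln1 by 7.74 and Rnase2a by 7.06. Genes that are typically made in liver also appeared: Mup20 and Mup7, major urinary proteins of a multigene family, had 0 counts in KO_saline and were at least 387-fold and 278-fold higher in KO_HDM, set against a floor of 3 counts over the group. Inmt fell from 1062 ± 188 to 110 ± 40.2 CPM, Pon1 by 3.14, Scgb1c1 by 3.06 and the scavenger receptor Marco by 2.80 on the log2 scale. Cyp1a1 (-6.35) rests on KO_saline 3, without which it was -3.04.

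Alternative macrophage activation genes rose in 12 of 14, with an adjusted p of 1.71e-14 and 0.00846 with an estimated correlation. All 16 goblet cell genes rose (adjusted p = 1.94e-09; 0.268 with an estimated correlation), as did all 20 cell cycle genes (2.63e-14; adjusted p = 0.214 with an estimated correlation). Type 2 genes were 9 higher and 1 lower of 16, with Ccl8 (6.23), Ccr3 (2.29) and Ccl11 (2.26) higher (adjusted p = 0.00923; 0.314 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 14 of 17 (15 adjusted over the list alone; adjusted p = 4.5e-13; 0.0616 with an estimated correlation), and alveolar macrophage markers were 7 higher and 3 lower of 16 (0.000414; adjusted p = 0.214 with an estimated correlation). MHC class II rose in 9 of 10 (all 10 adjusted over the list alone) and matrix genes in 16 of 20 (17 adjusted over the list alone), with adjusted p of 2.94e-05 and 1.94e-09, and 0.321 and 0.214 with an estimated correlation. B and plasma cell genes rose in 10 of 15 (11 adjusted over the list alone; Tnfrsf17 4.19; Igj 6.01, or 6.96 without KO_saline 4), T cell genes in 9 of 18 (Icos 2.58, Cd28 2.34) and interferon response genes in 14 of 21 with 1 lower (2 lower adjusted over the list alone; Cxcl10 2.89, Zbp1 1.55). Their adjusted p were 0.000366, 0.00923 and 0.00904, and 0.479, 0.668 and 0.484 with an estimated correlation. Eosinophil markers were again 6 higher and 2 lower of 9, but the list was not called (adjusted p = 0.302).

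Falling groups in the libraries labelled knockout were endothelial markers (17 of 19; Plvap -1.61, Kdr -1.32), club cell markers (9 of 12, with 1 higher adjusted over the list alone; Cyp2f2 -2.41, Cldn10 -1.43), ciliated markers (9 of 17, with 1 higher) and type 1 alveolar markers (9 of 14; 10 adjusted over the list alone). Their adjusted p were 1.04e-07, 7.83e-06, 0.00401 and 0.000366, and 0.321, 0.214, 0.484 and 0.484 with an estimated correlation. Mesothelial markers fell in 6 of 7, such as Upk3b (-2.03), with an adjusted p of 0.000366 and 0.314 with an estimated correlation. All 11 red blood cell genes fell here too, such as Hba-a1 (-1.98), with an adjusted p of 3.1e-08 and 0.284 with an estimated correlation; reads of globin genes may be shared with close copies. NK and cytotoxic genes fell in 5 of 12 (adjusted p = 0.0308; 0.484 with an estimated correlation), a call lost in 15 of the 20 fits that leave out 1 library, with adjusted p from 0.052 to 0.0929 there. edgeR called 8406 genes, with 4246 higher and 4160 lower, and 2366 changed at least 2-fold, 1655 higher and 711 lower. Of the 33 lists, 18 were called, and 1 with an estimated correlation. Groups did not overlap for 43.9% of genes, against 0.794% by chance.

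Both HDM responses had largely the same direction. Across the 16193 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.732, with an SD of 0.707 in wild type and 0.929 in knockout labels. The slope of the response in knockout labels on that in wild type was 0.961, and the opposite slope was 0.558. Both comparisons share no library. They shared 1954 genes called higher, where independent lists would share 576, and 2313 called lower, where 685 would be shared; 11 genes were called in opposite directions (4 higher and 7 lower in wild type).

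**Figure D2:**
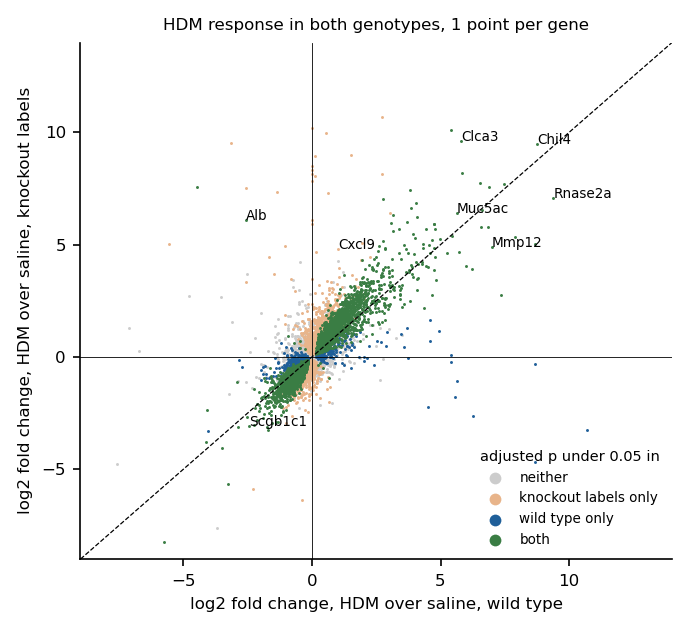
Log2 fold change of HDM over saline in wild type (horizontal) and in the libraries labelled knockout (vertical), 1 point per tested gene, coloured by where edgeR gave an adjusted p under 0.05; the dashed line marks equal change. Most genes called in both lie along the diagonal (r = 0.732 over all genes), and Alb lies away from it.

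Knockout against wild type under saline asks what differs between the genotypes without allergen. All 11 red blood cell genes rose in the libraries labelled knockout, among 96 genes called higher. Slc4a1, the anion exchanger of the red cell membrane, went from 12.62 ± 5.43 to 110 ± 49.9 CPM (SD, n = 5; log2 3.12 ± 0.30), and the globin Hbb-bs rose by 2.06. Outside that list, Epb4.2 (3.00), Trim10 (2.99), Apol11b (3.49), AA465934 (3.39) and the antiviral gene Rsad2 (2.03) were higher. Pttg1, a securin, fell from 27.8 ± 1.78 to 5.05 ± 1.14 CPM (log2 -2.46 ± 0.14), and Slfn8 (-2.05), Mki67 (-1.79), Suv39h2 (-1.67), Unc45b (-1.06) and Sp6 (-1.08) were lower. Erdr1, which lies in the region shared by the X and Y chromosomes, had a log2 change of -3.12 with an adjusted p of 0.0269; the call ended without any of 7 libraries (WT_saline 1, 2 or 3, adjusted p 0.0775, 0.0556 and 0.056, and KO_saline 1, 2, 3 or 5, adjusted p 0.052, 0.093, 0.1 and 0.0937).

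The red blood cell list had an adjusted p of 6.9e-74, and 0.000403 with an estimated correlation; it was the only list that kept its call there. Clock genes were 5 higher and 3 lower of 16 (8 and 4 adjusted over the list alone), with Dbp (1.96) higher and Npas2 (-1.34) and Arntl (-0.97) lower (adjusted p = 0.000897; 0.316 with an estimated correlation). Ferroptosis and glutathione genes (2 of 24, Gpx1 0.71 and Gclm 0.49) and neutrophil markers (1 of 13, Retnlg; 7 adjusted over the list alone) had upward calls, with adjusted p of 4.63e-06 and 1.48e-06 and 0.316 each with an estimated correlation. Gclm lost its call without KO_saline 2 (adjusted p = 0.0898) or KO_saline 3 (0.105). Of the goblet cell list only Clca3 passed (-4.28 ± 0.75, adjusted p = 0.00443), under a downward call of adjusted p = 0.000404 (0.678 with an estimated correlation) that was 0.705 without the 5 libraries rich in adipose transcripts. Clca3 itself had an adjusted p of 0.308 with limma voom, 0.119 with the 10 compared libraries alone and 0.0667 without those 5 libraries. Upward calls also came for type 2 alveolar (adjusted p = 1.66e-06), mesothelial (3.18e-05), endothelial (0.000587), type 1 alveolar (0.00729) and club cell (0.0127) markers, and downward calls for B and plasma cell (0.000898), smooth muscle (0.00445) and cell cycle (0.0277) genes. Over all genes no member of these passed except Mki67, and adjusted over the list alone 3 mesothelial and 3 B cell genes passed. In the same order their p were 0.573, 0.316, 0.702, 0.78, 0.665, 0.702, 0.702 and 0.829 with an estimated correlation. Without WT_saline 4 the adjusted p of the B cell, cell cycle and type 1 alveolar lists were 0.123, 0.795 and 0.126. Without WT_saline 2 those of the smooth muscle and type 1 alveolar lists were 0.299 and 0.111. The cell cycle list was also lost without KO_saline 1 (0.19) or KO_saline 5 (0.0621), and the club cell list without WT_saline 1 (0.0675), WT_saline 3 (0.132) or KO_saline 2 (0.0613). The mean of the club cell list, 0.05, was -0.02 without WT_saline 1 or KO_saline 2.

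edgeR called 147 genes, 96 higher and 51 lower, of which 80 changed at least 2-fold. DESeq2 called 327, and 95 of the genes outside chromosome 11, which carries Alox15, were called when tested alone. Groups did not overlap for 3.06% of genes, against 0.794% by chance. Of 36 tested genes near Alox15, Nlrp1a was called under saline (-0.91).

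**Figure D3:**
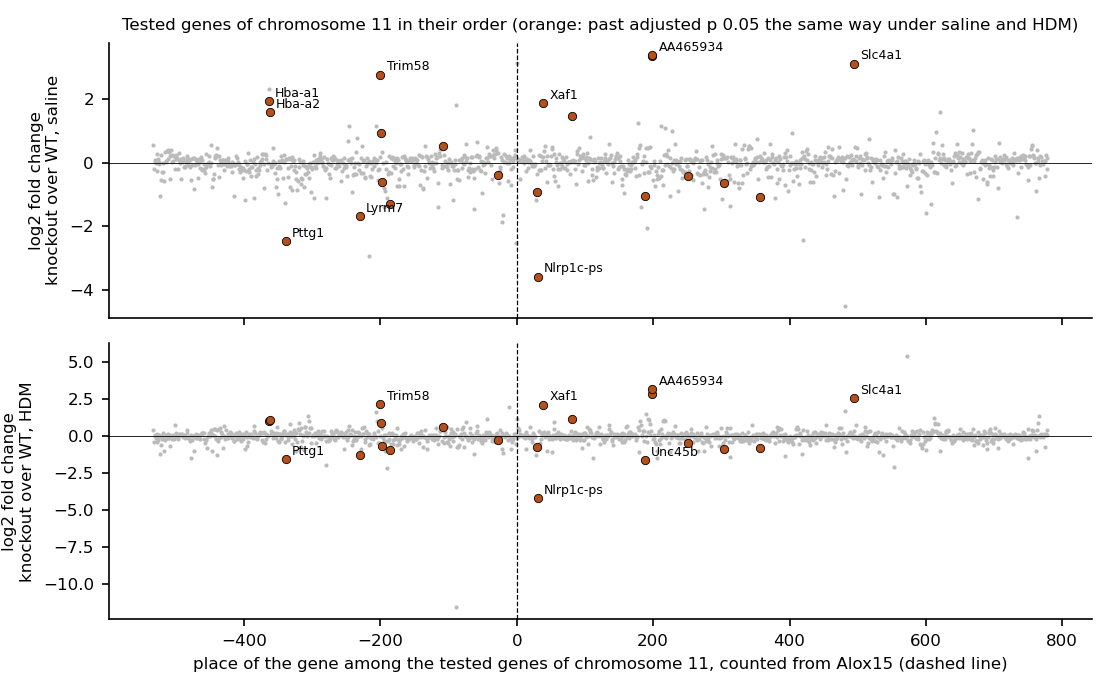
Log2 fold change of knockout over wild type under saline (top) and HDM (bottom) for the tested genes of chromosome 11 in their order, counted from Alox15 (dashed line). Orange points mark the 21 genes called in the same direction under both treatments, 10 higher and 11 lower.

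The comparison that the series design names is knockout against wild type under HDM. Several neutrophil, macrophage and interferon genes were higher in the libraries labelled knockout. Cxcl10, an interferon-induced chemokine, rose by 2.21 ± 0.39 on the log2 scale, Rsad2 by 1.52 and Gbp2 by 1.11. The neutrophil granule genes Ngp (2.61 ± 0.52) and Mmp8 (1.52 ± 0.27), the formyl peptide receptor Fpr2 (2.08 ± 0.30) and the macrophage gene Emr1, now Adgre1, which went from 49.0 ± 6.17 to 144 ± 39.4 CPM (SD, n = 5), rose as well. Of type 2 genes, the interleukin-33 receptor Il1rl1 was lower, at 17.0 ± 3.96 and 9.68 ± 1.80 CPM (log2 -0.81), and so were the remodelling proteases Mmp13 (-2.54) and Mmp28 (-1.50), the natriuretic peptide clearance receptor Npr3 (-1.65) and the lectin Mgl2 (-0.91).

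Neutrophil markers rose in 6 of 13 (9 adjusted over the list alone; adjusted p = 3.13e-07; 0.186 with an estimated correlation). The neutrophil list was also called upward under saline, and its interaction was not called (camera adjusted p = 0.452). S100a8 (1.88) lost its call without KO_HDM 4 (adjusted p = 0.0621). Monocyte and interstitial macrophage markers rose in 10 of 17 (14 higher and 2 lower adjusted over the list alone), such as Emr1 (1.56), Ms4a7 (1.28) and Cx3cr1 (1.05) (adjusted p = 9.19e-10; 0.0978 with an estimated correlation). Interferon response genes rose in 8 of 21 (10 adjusted over the list alone; adjusted p = 3.13e-07; 0.239 with an estimated correlation); Cxcl9, at 5.96 ± 1.82 and 45.7 ± 23.6 CPM, had an adjusted p of 0.0235, which was 0.06, 0.053, 0.0562 and 0.0708 without WT_HDM 4, WT_HDM 5, KO_HDM 3 or KO_HDM 4. Eicosanoid pathway genes rose in 5 of 28 (6 adjusted over the list alone), with Fpr2, Alox5ap (0.86) and Tbxas1 (0.74), under an adjusted p of 0.0338 (0.415 with an estimated correlation) that was 0.08 without WT_HDM 4 and 0.0559 without KO_HDM 2. Cell cycle genes had 1 higher and 1 lower member of 20 (3 and 1 adjusted over the list alone; Mki67 -1.21) under an upward call, and matrix genes 2 higher of 20 (with 1 lower adjusted over the list alone; Fn1 0.84); their adjusted p were 0.000165 and 0.00851, and 0.677 and 0.671 with an estimated correlation. No T cell marker passed, and the list's adjusted p of 0.0387 (0.914 with an estimated correlation) was 0.18, 0.11 and 0.0588 without WT_HDM 5, KO_HDM 1 or KO_HDM 4.

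Mast cell and basophil genes were lower as a list (adjusted p = 0.0022; 0.0595 with an estimated correlation) with 1 of 10 past the test (2 adjusted over the list alone), Mcpt1 (-2.01), whose adjusted p of 0.0215 was 0.0783, 0.0616 and 0.0606 without WT_HDM 3, KO_HDM 3 or KO_HDM 4. Mesothelial markers were lower with no member past the test (1 adjusted over the list alone; adjusted p = 0.0167; 0.642 with an estimated correlation), and 0.0508 without WT_HDM 2 and 0.11 without KO_HDM 1. The type 2 list was not called (adjusted p = 0.0654; 3 of 16 lower), nor were the goblet cell (0.456; 0 of 16) and eosinophil (0.0751; 0 of 9) lists. Ccl24 lay at 10.2 ± 6.11 CPM in WT_HDM and 1.62 ± 1.51 CPM in KO_HDM (adjusted p = 0.0198; 0.0554 without KO_HDM 2 and 0.0684 without KO_HDM 4, and log2 -2.66, or -3.34 without KO_HDM 5). Ferroptosis and glutathione genes were 2 higher and 1 lower of 24 (Fth1 0.72, Gpx3 -0.91), and that list was not called.

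Markers of other tissues moved with the group in this comparison. All 11 red blood cell genes were higher in KO_HDM (Slc4a1 2.55; adjusted p = 2.17e-22; 0.0595 with an estimated correlation). Liver transcripts were present in all 5 KO_HDM libraries: albumin (Alb) lay between 20.1 and 76.4 CPM there and at most at 1.10 CPM in the other 15 libraries, and Mup7 was at least 213-fold higher than in WT_HDM, where it had 0 counts. Of a liver marker list made after the data were seen, 24 of 32 members were higher. The Rn45s share was 1.82% to 2.98% in KO_HDM against 2.72% to 6.08% in WT_HDM. Skeletal muscle genes were lower in 5 of 7, with WT_HDM 2 the only library with Ckm above 46.4 CPM, and the list was not called (adjusted p = 0.0708). Adipoq was at 50 CPM or more in 5 libraries, WT_saline 2, WT_saline 4, WT_HDM 2, WT_HDM 4 and KO_HDM 5.

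edgeR called 1080 genes, 775 higher and 305 lower, of which 168 and 84 changed at least 2-fold; limma voom called 2239. Without KO_HDM 4 or KO_HDM 3 the count was 576 or 663. Of the 33 lists 10 were called, and 0 with an estimated correlation by camera. Taking each list's mean log2 CPM per library, 8 lists had an exact two-sided permutation p under 0.05 and 0 passed adjustment over the 33 lists. The lowest exact p, 0.00794 (adjusted 0.0524, n = 5), went to neutrophil (1.10), interferon (0.58), monocyte and interstitial macrophage (0.58), red blood cell (1.39) and eosinophil (-0.39) markers, for which WT_HDM and KO_HDM libraries did not overlap. Genes without overlap made up 7.01% of those tested, against 0.794% by chance. Between the saline and HDM comparisons of genotype, which have no library in common, 47 genes were higher in both (4.59 by chance). Lower in both were 19 genes (0.961 by chance), and 0 were called in opposite directions. Over all genes the log2 fold changes of these comparisons correlated with only r = 0.178. Over the 1161 genes called in either, r was 0.0798 and 60.3% had the same sign. Over the 147 called under saline, r was 0.819.

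**Figure D4:**
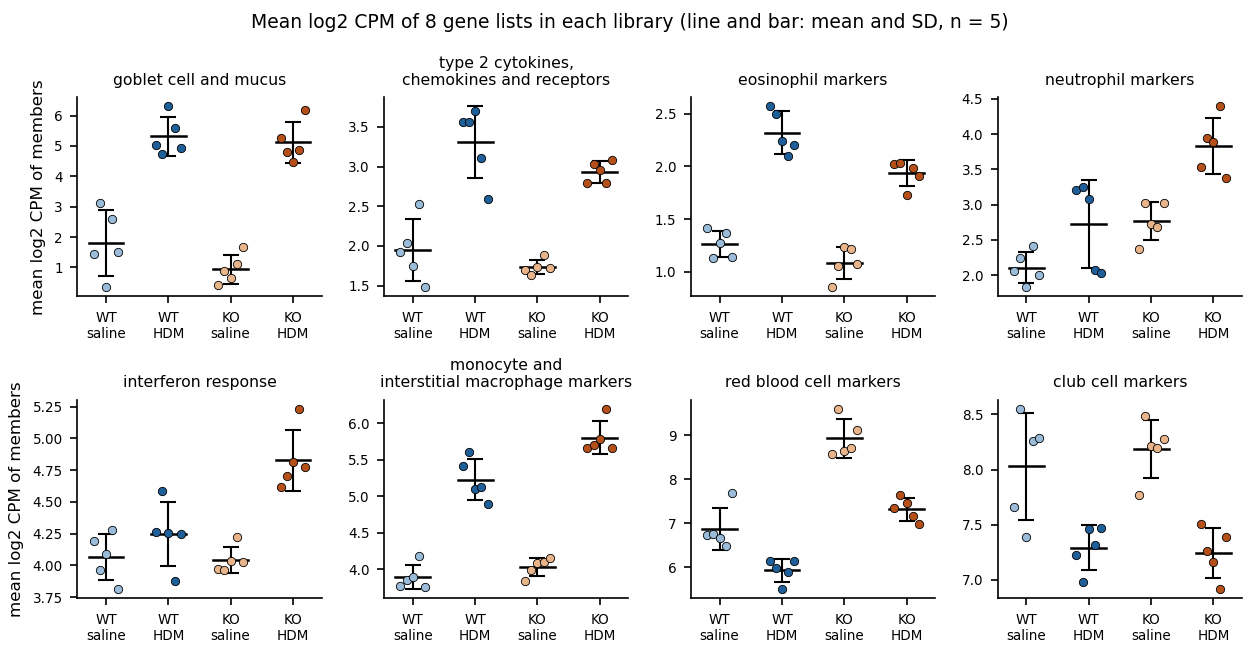
Mean log2 CPM over the measured members of 8 gene lists in each library, by group, with the mean and SD of 5 libraries. Neutrophil, interferon and monocyte lists lie higher in KO_HDM than in WT_HDM (differences of 1.10, 0.58 and 0.58), and the goblet cell list overlaps between them.

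Whether the response to HDM differs between genotypes was tested as an interaction. Emr1 rose more under HDM in the libraries labelled knockout (interaction 1.61 ± 0.22 on the log2 scale, adjusted p = 0.00109), as did Fpr2 (2.31 ± 0.42), the lipopolysaccharide-degrading enzyme Aoah (1.93 ± 0.31), the Fc receptor Fcgr1 (1.81 ± 0.35) and Gbp10 (2.74 ± 0.50). Liver transcripts differed as well, with Alb at 8.66 (9.32 without WT_HDM 2) and Pzp at 4.26. Mmp12 rose in both genotypes and by a smaller fold in the libraries labelled knockout (interaction -2.08 ± 0.37). Its counts, summed over the group and not scaled to depth, were 588 in WT_saline and 1601 in KO_saline. WT_HDM held 62761 and KO_HDM 42033, so a higher level under saline in the libraries labelled knockout is part of this interaction. Lgals2 (-2.28), Klhl29 (-1.52), Atp6v0a4 (-1.38) and the clock repressor Nr1d1 (-1.34) had negative interactions. HDM lowered them in the libraries labelled knockout (by 2.44, 1.35, 1.18 and 1.66), while they did not pass in wild type. Summed over the group and not scaled to depth, their counts were 540, 1604, 981 and 25817 in KO_saline. WT_saline held 259, 928, 691 and 12028, so a higher level under saline is part of these interactions. The platelet receptor Clec1b (-1.43) rose in wild type (1.17) and did not pass in knockout labels, and P2rx1 (-1.59) rose in wild type (0.67) and fell in knockout labels (-0.92).

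Of 15 lists called, 6 had a positive interaction, with a change under HDM that lay higher in the libraries labelled knockout. These were cell cycle (adjusted p = 4.61e-07, 0 of 20 members past the test and 1 adjusted over the list alone), interferon (2.69e-05, 1 of 21 and 7), monocyte and interstitial macrophage (0.00013, 1 higher and 1 lower of 17, and 10 higher adjusted over the list alone), matrix (0.00059, 1 lower of 20, and 10 higher adjusted over the list alone), T cell (0.000923; 0.22 without WT_saline 4) and goblet cell genes (0.0426, 0 of 16 and 1). With an estimated correlation their p were 0.509 for the first 4, 0.711 and 0.723, and 0 of the 15 passed. The goblet cell call ended without any of 10 libraries, with adjusted p between 0.0796 and 0.329, and its mean of 1.08 turned to -0.52 without the 5 libraries rich in adipose transcripts. Negative interactions were called for mesothelial (1.69e-07), red blood cell (6.63e-06), endothelial (3.56e-05), type 2 alveolar (0.00135), ferroptosis and glutathione (0.00176), skeletal muscle (0.00429; 0.113 without WT_HDM 2), type 1 alveolar (0.00636), clock (0.0106; 0.0538 without WT_saline 4) and club cell (0.0151) lists, with p between 0.47 and 0.711 with an estimated correlation. Adjusted over the list alone, 6 of 7 mesothelial, 6 of 7 skeletal muscle, 4 of 19 endothelial and 5 of 16 clock genes (with 2 higher) were lower. The type 1 alveolar call was lost without WT_saline 2, WT_saline 4, WT_HDM 5 or KO_HDM 5 (adjusted p 0.0501, 0.0558, 0.118 and 0.074), and the club cell call without WT_saline 1, WT_saline 3, WT_HDM 5 or KO_HDM 4 (0.0712, 0.0878, 0.0501 and 0.0634). The interaction of Alox15 was -2.0 ± 0.59 with adjusted p = 0.106, and -2.66 with adjusted p = 0.0183 without WT_saline 2. edgeR called 200 genes, 162 higher and 38 lower, and 85 at least 2-fold, 65 higher and 20 lower. That number rests on single libraries: it was 79 without KO_HDM 4, 95 without KO_saline 2, 112 without KO_saline 3, 116 without WT_saline 1, 117 without KO_HDM 3, 122 without WT_HDM 4 and 130 without KO_saline 5.

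**Figure D5:**
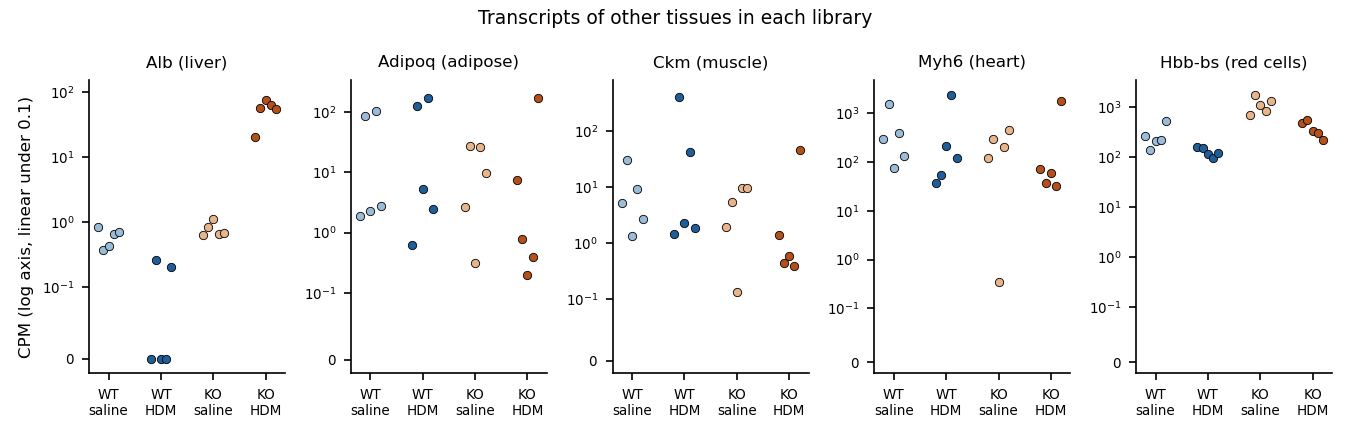
CPM of Alb, Adipoq, Ckm, Myh6 and Hbb-bs in each library, by group, on a log axis that is linear under 0.1 CPM; each point is a library. Alb is between 20.1 and 76.4 CPM in KO_HDM and at most 1.10 CPM elsewhere, and Adipoq, Ckm and Myh6 vary between libraries of the same group.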

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

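The tests of single libraries and the gene lists they use were fixed in advance. How the flagged lists are gathered below, such as under lymphoid genes, was chosen after the values were seen. A library whose level of a gene list lay far from the other 4 of its group was found in 19 of 136 groups of libraries, where chance gives about 1 in 20, or 6.8. WT_saline 4 was high for lymphoid genes in log2 CPM: B and plasma cell (4.96; next highest 3.20), T cell (4.29; 1.93), thymocyte (3.40; 2.57), dendritic cell (3.91; 3.11), MHC class II (7.24; 6.15) and cell cycle (3.94; 3.10). KO_saline 4 was high for B and plasma cell (3.87; 2.59), T cell (3.04; 1.83), interferon (4.22; 4.04) and skeletal muscle (2.77; -0.50) genes. WT_saline 2 was high for smooth muscle (6.91; 5.61), WT_saline 5 for red blood cell (7.70; 6.76) and WT_HDM 2 for skeletal muscle genes (8.25; 0.41). KO_HDM 5 was high for cardiac muscle (6.72; 2.99), smooth muscle (5.88; 4.82), alternative macrophage activation (6.95; 6.58) and alveolar macrophage genes (6.30; 5.72) and low for NK and cytotoxic genes (1.16; 1.69). KO_HDM 4 was high for monocyte and interstitial macrophage genes (6.20; 5.79).

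The response to HDM differed between genotypes for 15 lists and for 24 named genes. Mean log2 interactions were higher in the libraries labelled knockout for T cell (1.24; 0.19 without WT_saline 4), goblet cell (1.08; 0.0076 with voom and -0.52 without the 5 libraries rich in Adipoq), cell cycle (0.70), interferon (0.64), monocyte and interstitial macrophage (0.46) and matrix genes (0.39). Lower means came for skeletal muscle (-8.50; -1.94 without WT_HDM 2, -6.22 without KO_saline 4 and -9.28 without KO_HDM 5), mesothelial (-0.94), red blood cell (-0.65), endothelial (-0.64), type 2 alveolar (-0.38), type 1 alveolar (-0.29), ferroptosis and glutathione (-0.23), clock (-0.23) and club cell genes (-0.10). With an estimated correlation camera called 0 of these 15 lists.

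Among genes, the interaction was positive for Alb (8.66; 9.32 without WT_HDM 2), Pzp (4.26), Gbp10 (2.74), Fabp1 (2.68), Fpr2 (2.315), Aoah (1.93), Gpr141 (1.86), Fcgr1 (1.81), Slfn8 (1.61), Emr1 (1.61), Hhip (1.16), Npas2 (1.12) and Gbp3 (1.07). It was negative for Lgals2 (-2.28), Mmp12 (-2.08), Map3k6 (-1.63), Dbp (-1.61), P2rx1 (-1.59), Myrip (-1.56), Klhl29 (-1.52), Clec1b (-1.43), Atp6v0a4 (-1.38), Nr1d1 (-1.34) and Retnlg (-1.31). Counts summed over the group and not scaled to depth, wild type first, were 2451 and 665 for Slfn8 under saline. Under HDM they were 2048 and 1740. Dbp had 1949 and 8459 under saline and 4048 and 5770 under HDM, and Npas2 1489 and 671, then 430 and 415. For these genes the genotypes differed more under saline than under HDM. Fpr2 went the other way, with 469 and 459 under saline and 664 and 3217 under HDM. Single libraries end the call for 6 of the genes with an interaction. The adjusted p of Dbp was 0.0525 without KO_HDM 4. That of Map3k6 was 0.0557, 0.0535 and 0.0668 without WT_saline 1, WT_HDM 4 or KO_HDM 4, and that of Gbp3 was 0.0667, 0.06, 0.0537 and 0.0641 without WT_saline 1, WT_HDM 4, KO_saline 2 or KO_HDM 4. Slfn8 had 0.0524, 0.0554, 0.0539, 0.0521 and 0.0642 without WT_saline 1, KO_saline 2, 3 or 5, or KO_HDM 4. Npas2 lost its call without WT_saline 1, 2 or 3, KO_saline 2 or 3, or KO_HDM 1 or 4 (0.0523 to 0.0846), and Hhip without WT_saline 1, 2 or 3, WT_HDM 1, 2, 3 or 4, KO_saline 2, 3 or 5, or KO_HDM 2, 3 or 4 (0.0567 to 0.108).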

How the results depend on the processing

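Of 378 results for named genes under 12357 alternatives, 11893 kept direction and side of the threshold, 441 were weaker, 6 stronger and 17 reversed. For the 72 called lists 2277 of 2441 alternatives were the same, 162 weaker and 2 reversed. For HDM against saline in wild type 2854 genes were called with the 10 compared libraries alone, 1077 at 2-fold or more and 2746 at an adjusted p under 0.01, and 2366 at 2-fold or more in knockout labels. For knockout under saline 327 were called by DESeq2, 95 outside chromosome 11, 80 at 2-fold or more and 91 under 0.01. For knockout under HDM 2239 were called by limma voom, 168 higher and 84 lower (2.5e2 together) at 2-fold or more and 398 under 0.01, and leaving out a library gave 576 (KO_HDM 4) to 1396 (WT_saline 1), with 663 without KO_HDM 3. For the interaction 608 were called by DESeq2, 363 by voom, 103 without the 5 libraries rich in Adipoq, 468 with an adipose covariate, 85 at 2-fold or more and 32 under 0.01, and leaving out a library gave 79 (KO_HDM 4) to 260 (WT_saline 5), with 95 and 112 without KO_saline 2 or 3, 116 without WT_saline 1, 117 without KO_HDM 3, 122 without WT_HDM 4 and 130 without KO_saline 5. Lists called with an estimated correlation were 1, 1, 1, 0 and 0 in the order above. Without the Adipoq libraries 8 lists were called for knockout under saline, and voom called 9 for the interaction. The goblet cell interaction was 0.0076 with voom and -0.52 without the Adipoq libraries. Under HDM in wild type Myh1 was -0.31 with voom, -3.84 without the Adipoq libraries and -3.02 without WT_HDM 2 (9.05 without WT_HDM 1), and Tnnt3 was -0.35 without the Adipoq libraries and -0.53 without WT_HDM 2 (6.33 without WT_saline 2). For knockout under HDM Myh1 was 0.59 without the Adipoq libraries and 0.18 without WT_HDM 2 (-11.91 without WT_HDM 4). The uncalled Alox15 difference between HDM and saline in knockout labels was -0.0056 with upper-quartile factors, -0.019 with a replicate block and -0.0692 to 0.0856 without single libraries, and its log2 level difference -0.0325 to 0.062. The cause was not tested, except that stricter thresholds call fewer genes by construction. Equal replicate numbers correlated at -0.429 to 0.506, over 0.1 in 12 of 20 pairs, 4 of 5 of them for HDM in wild type and for knockout under saline. As not every pair passed 0.1 and not every sample correlated best with its own number, they were not taken as pairs, and a block called 5058, 8584, 160, 1047 and 246 genes. Upper-quartile factors made 61.8% of calls higher for knockout under HDM (71.8% with TMM) and 71.0% for the interaction (81.0%). The correlation of both HDM responses was 0.652 to 0.731 without single libraries, and gene length correlated with the changes at -0.085 to 0.00738. The fits around adipose transcripts and chromosome 11 were chosen after the data were seen, and genes with too few counts for the filter were not tested.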

Other observations

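The groups and tests of this part were chosen after the data were seen. Genes of the unfolded protein response and of export from the endoplasmic reticulum, the compartment that folds secreted proteins, rose with HDM. In wild type 20 of 29 were higher (camera p = 9.98e-11; 0.0291 with an estimated correlation), such as Derl3 (2.18), which helps remove misfolded proteins, the chaperone cofactor Sdf2l1 (1.51), Edem1 (1.09), Manf (0.89), the chaperone Hspa5 (0.67) and the transcription factor Xbp1 (0.50). In the libraries labelled knockout 24 were higher and 1, Ddit3 (-0.27), lower (p = 2.41e-09; 0.0408 with an estimated correlation), with Derl3 at 3.16, Edem1 at 1.73 and Ube2j1 at 1.01. Between genotypes under HDM 8 were higher in the libraries labelled knockout (p = 3.92e-06; 0.105 with an estimated correlation), such as Derl3 (0.97), Ube2j1 (0.71) and Edem1 (0.56). Under saline edgeR called 0 of 29. Genes of secretory cells rose with HDM in the same comparisons, with 6 and 10 of 15 B and plasma cell genes and 15 and 16 of 16 goblet cell genes higher in wild type and in knockout labels. The interaction was called for Ube2j1 (0.78) and Edem1 (0.64), with a list p of 0.00462 and 0.307 with an estimated correlation.

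Genes that differed between genotypes in the same direction under saline and under HDM numbered 66. Of these 45 lie outside chromosome 11, 37 higher and 8 lower in the libraries labelled knockout, and 8 of them are red blood cell markers. Further genes of the erythroid lineage, such as the blood group gene Kel (3.62 under saline and 2.97 under HDM), Rhag (2.74 and 1.98) and Tspo2 (3.17 and 2.40), moved with them. Others are the ubiquitin-like conjugating enzyme Ube2l6 (1.34 and 0.74), Dynlt1b (1.17 and 1.41) and the macrophage receptor Trem2 (1.10 and 0.69), with Entpd4 (-1.01 and -0.91) and Rab44 (-0.93 and -1.02) lower.

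Liver transcripts appear in all 5 KO_HDM libraries: 20 of 32 measured liver markers were above every one of the other 15 libraries, and their sum was 51.0 to 170 CPM against at most 5.05 CPM. RNA of liver mixed into these samples would keep the markers in proportion to each other. Across the 5 libraries the median variance of a marker relative to the sum of the rest was 0.0350, against 0.518 for its level, but without KO_HDM 1 these were 0.0295 and 0.0374, so the test cannot tell. Transcription in lung under HDM in these mice would also raise the 24 markers called, and the tables hold no measure of where the RNA was made. Both explanations stay open.

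On chromosome 11, which carries Alox15, 21 of 1312 genes (1.60%) were called the same way in both treatments, against 0.304% elsewhere, and without the fixed red blood cell list 18 of 1309 against 37 of 14795 (one-sided Fisher p = 1.68e-07). DNA of another mouse strain kept around Alox15 after backcrossing may explain this share. Poorer matching of reads from another strain to the reference would lower counts. Of the 18, 7 were higher, 5 of them beside the erythroid genes Trim58 and Slfn14. This argues against poorer matching as the whole cause, unless reads moved to close copies of a gene. The fixed list of genes near Alox15 gave 5 of 36 called in either treatment against 7.15% (one-sided Fisher exact p = 0.112), which cannot tell. Of the 100 nearest tested genes on each side 12.0% were called in either treatment against 7.10% elsewhere (Fisher exact p = 0.00886), and 2.50% in both against 1.44% on the rest of chromosome 11 (Fisher exact p = 0.2055). How far such DNA reaches stays open. Without the fixed red blood cell list the genes spread from Pttg1 on one side of Alox15 to Sp6 on the other. Their places among the tested genes, counted from Alox15, were -339 and 356.

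Alox15 was higher in the libraries labelled knockout by 3.15 on the log2 scale under saline. Single exchanged labels were not seen: when genes called in one treatment scored the libraries of the other, 0 of 20 were out of place. The gap between genotypes in this score was 0.468 among HDM libraries and 0.0582 among saline libraries. The score therefore separates the saline libraries only narrowly and cannot by itself exclude an exchange there. Alox15 itself lay at 0.825 to 11.1 CPM in WT_saline and 38.4 to 44.7 CPM in KO_saline. A single exchanged saline library would lie in the range of the other group, so these values argue against single exchanges under saline. An exchange of all genotype labels may give the same picture, and no other value in the tables marks the genotype. Transcription from a disrupted allele under other control may do so too. Its test cannot tell, as the interaction of Alox15 (-2.0) did not pass in edgeR (adjusted p = 0.106). Without WT_saline 2 it did pass, as given above, so a single library decides that outcome. Neither can be told apart with counts per gene.

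Regrouping the same libraries at random, 100 splits per comparison with the real one included, tested whether chance groups call as many genes. For HDM against saline 2 splits reached the 4866 genes of wild type (highest other 5176, exchanging WT_saline 4 and WT_HDM 5), and 1 reached the 8406 in knockout labels (highest other 2). For knockout against wild type 2 splits reached the 147 genes under saline (highest other 375, exchanging WT_saline 4 and KO_saline 1). Under HDM 2 splits reached the 1080 genes (highest other 1506, exchanging WT_HDM 1 and 5 with KO_HDM 1 and 5). In that split, WT_HDM 1 and 5 with KO_HDM 2, 3 and 4 had at most 2.48 CPM of Adipoq, and the other group at least 5.36 CPM. Type 2 alveolar scores were at least 9.74 and at most 9.52 log2 CPM in the same order. Other lists were not compared in this way. For the interaction the genotype labels were shuffled within each treatment, and only the real split reached 200 (highest other 25). Shuffling them removes the genotype difference as well as the interaction, so this count cannot exclude chance for the interaction alone. In each of the other comparisons at most 2 of the 100 splits reached the real count, a share under 0.05 without adjustment over the comparisons. In 3 of these comparisons a single other split called more genes than the labels did. The count alone therefore does not show that the labels, and not an uneven content of tissue, separate the libraries there. Splits close behind called 4368 genes for HDM in wild type (exchanging WT_saline 1 and WT_HDM 5) and 993 for knockout under HDM (exchanging WT_HDM 1 and KO_HDM 5). Why these splits call so many genes was not tested.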
